A study of Homo sapiens with 2 samples.

How the data were processed

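RNA bound by RBM39 was mapped in wild-type MCF-7 cells, an established human breast adenocarcinoma line, by crosslinking and immunoprecipitation followed by sequencing (CLIP-seq). RBM39 is a splicing factor with an arginine- and serine-rich domain that is related to U2AF2, the protein that recognises the polypyrimidine tract upstream of 3' splice sites. The series held 2 libraries, 1 made with an antibody against RBM39 and 1 made with IgG. Per the labels' protocols, cells were irradiated at 254 nm with 400 mJ per square cm, 10 ug of antibody was used with 300 ul of lysate, RNA was trimmed with micrococcal nuclease for 15 min, and libraries of 150 to 250 bp were made with the TruSeq Small RNA kit and sequenced on an Illumina NextSeq instrument. Reads were aligned with TopHat2 2.0.6 to GRCh38, per the submitters' processing notes. The peak caller, its thresholds, the use made of the IgG library and the annotation release were not given in the sources used here.

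The deposited file was a list of peaks for the RBM39 library. Per the file headers, it gave for each peak a position and strand, the number of reads (a whole count), the greatest read depth inside the peak (a signal, called height below), the width, the summit, a transcript region and a gene identifier. Neither the counts nor the signal had been scaled to library size by the authors. The total number of reads in the library was not in the file, so no share of the library can be given. The IgG library was not analysed here, since its values were not in the list, and background binding is unknown. A peak that IgG would also give cannot be recognised from the list, and heights follow RNA abundance as well as binding because no expression level was in hand.

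Positions were counted from 1 with both ends included. The region at the centre of each peak was taken from the comprehensive GENCODE 29 annotation of GRCh38 over all genes on the same strand, in the order coding exon, 5' UTR, 3' UTR, non-coding exon, intron, and antisense or outside genes. Of the 1271 peaks, 1258 carried a gene identifier that matched GENCODE 29 when version numbers were ignored, and 1006 matched with the version. The host gene of a peak was the longer gene around it rather than a small RNA inside that gene. Names and ends of small nucleolar RNAs (snoRNAs) came from the RefSeq gene table of GRCh38.p14 where it placed one at the peak centre, and otherwise from GENCODE. This added snoRNAs missing from GENCODE, such as SNORD74 and SNORD31. The RefSeq positions carried no strand, so these matches did not check the strand of the snoRNA. "Structural RNA" below means all peaks on the mitochondrial genome and those on snoRNAs, Cajal body RNAs, snRNAs, rRNAs and their pseudogenes, vault RNAs, ribozymes such as RMRP and RPPH1, and genes that GENCODE types as miscellaneous RNA, such as 7SK, 7SL and their copies.

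With 1 library per antibody nothing could be tested across replicates, and no p-value is given. Shares of peaks carry exact (Clopper-Pearson) 95% binomial intervals over peaks. They cover counting error only, since reads without molecular identifiers are not independent molecules. Shares were set beside 1000 placements of each peak at a random position in its host gene, which hold the gene and the width, and for splice sites also beside 1000 placements in the same region type of the host gene. Splice sites were counted within 100 nt of the peak centre. Hexamers on the transcribed strand were set beside 100 placements in the same region type, with sequence from annotated transcripts. A genome sequence was not used here, so no intronic peak, and no peak with a base outside annotated exons, entered the hexamer counts. Numbers of genes with a peak in 15 fixed lists holding 386 entries were set beside 10000 random lists matched on gene biotype and on gene length in 10 classes. Expression was not matched, so an excess also reflects how strongly the listed genes are transcribed.

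The lists, the hexamers, the comparisons and the rule for named genes were fixed before the data were examined. The rule took RBM39, the 10 genes with most peaks, the genes of the 10 tallest peaks and up to 4 members of each list with most peaks, ties going to the taller peak. Genes named outside it are marked as such. Alternatives fixed with it were the 635 tallest peaks, merged overlapping peaks, the region over most of the peak, the authors' region and gene columns, 1 peak per gene, peaks off structural RNA, windows of 50 and 200 nt, and flanks of the same width as background for hexamers. Added after seeing the data were the GENCODE basic transcript set, peaks of at least 25 nt, peaks outside the mitochondrial genome, peaks off structural RNA for splice sites, lists and hexamers, and peaks without adapter words. The count of peaks that cross a splice site, with at least 5 nt on each side, was also added after seeing the data, as was the search for 8 nt words of the kit's adapters, which used 100 shuffled adapters and the flanks of peaks as background.

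The counts were tested on simulated data, after the first look at the real peaks. Of the 5 regions, 5 had a ratio whose interval held 1 for peaks placed uniformly in their host genes. With 292 peaks planted near 3' splice sites on the intron side, an excess of 275 was recovered. Of 100 random gene lists, 2 had a count reached by under 5% of draws. When 164 peaks were moved onto the hexamer TTTCTT its ratio was 6.20, against 0.944 for the peaks as listed. All 50 peaks set over a 3' splice site were found, which brought the count from 14 to 64. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.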

Results

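The list for the RBM39 library held 1271 peaks that covered 49860 nt and contained 7527 reads. Peaks held 3 to 100 reads with a median of 4, and their heights ran from 3 to 30 with a median of 4. Widths ran from 5 to 318 nt with a median of 28 nt. Most peaks rested on few reads: 540 peaks (42.5%) held 3 reads and 311 held 4. The 155 peaks with 10 or more reads made up 12.2% of peaks and held 40.6% of the reads in peaks. There were no replicates and no values for the IgG library, so every number below describes this library alone.

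Where RBM39 was recovered on RNA was asked first. The tallest peaks lay on small nucleolar RNAs, the guides of rRNA methylation and pseudouridylation that are processed mostly from introns. All 10 of the 10 tallest peaks and 20 of the 20 tallest lay on a snoRNA or a related Cajal body RNA, as did 80 of the 100 tallest. The tallest was on SNORD74 in an intron of GAS5 (GRCh38, chromosome 1, 173867674 to 173867744, minus strand), with 40 reads and a height of 30. SNHG1, a non-coding host gene on chromosome 11, had 9 peaks, 8 of them on snoRNAs, with heights of 27 on SNORD25, 26 on SNORD31 and 25 on SNORD26. Next came SNORD52 in C6orf48 with a height of 25, SNORD100 and SNORA33 in RPS12 with 23 each, SNORD2 in EIF4A2 with 23, SNORD58C in RPL17 with 23, and SNORD118 (U8) at TMEM107 with 22.

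In all, 149 peaks (11.7%, 95% interval 10.0 to 13.6) lay on 131 snoRNAs or Cajal body RNAs in 81 host genes. RNAs outside longer genes, such as SNORD13, were counted as their own host. The 149 peaks held 2437 reads, 32.4% of the reads in peaks. Their median height was 10, against 4 for the other 1122 peaks. Box C/D RNAs, which guide methylation, had 91 peaks with a median height of 13. Box H/ACA RNAs, which guide pseudouridylation, had 41 with a median of 7. Peaks on box C/D RNAs followed the mature RNA: 49 of 91 (53.8%, 43.1 to 64.4) had both ends within 5 nt of it, against 3 of 41 on box H/ACA RNAs (7.32%, 1.54 to 19.9). Median peak widths were 73 nt on box C/D and 69 nt on box H/ACA RNAs. Peaks covered a median of 98.5% and 48.8% of the RNA, so the contrast also reflects RNA length, which was not matched. Introns of 20 cytosolic ribosomal protein genes carried 37 of the snoRNA peaks.

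**Figure D1:**
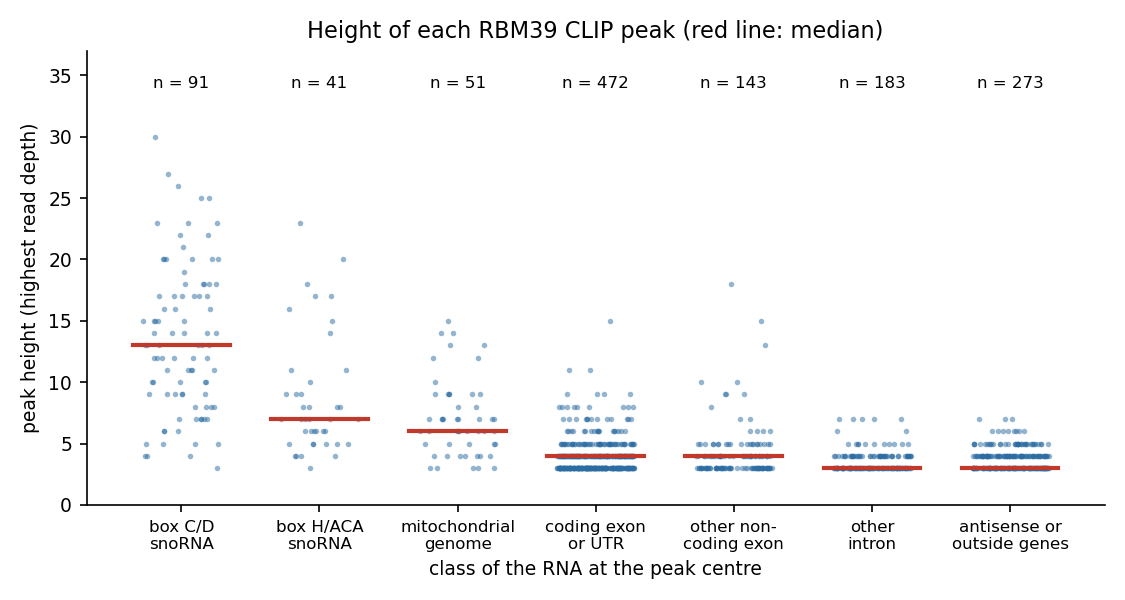
Height of each RBM39 CLIP peak, the greatest read depth inside it, by class of the RNA at its centre. Points are peaks, red lines are medians, and n is the number of peaks; box C/D snoRNA peaks have a median height of 13 and reach 30, and peaks in coding exons or UTRs have a median of 4.

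**Figure D2:**
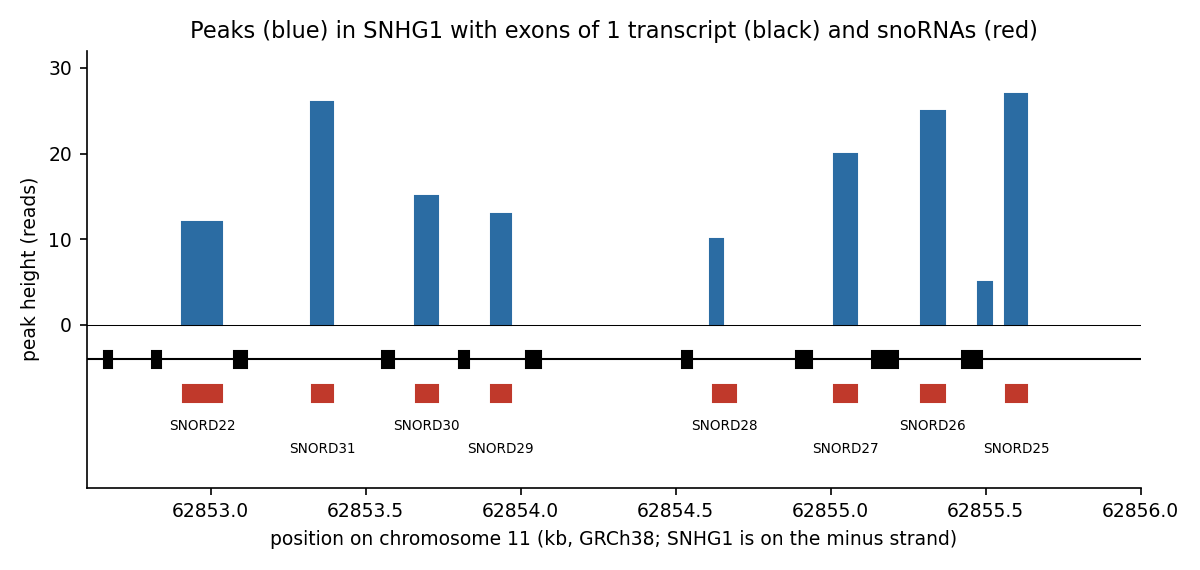
Map of SNHG1 on chromosome 11 (GRCh38, minus strand), with position in kb on the horizontal axis and peak height in reads on the vertical axis. Blue bars are peaks to scale, black boxes are exons of 1 annotated transcript and red boxes are snoRNAs; 8 of the 9 peaks lie on a snoRNA.

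Peaks lay in exons of messenger RNA more often than random positions in the same genes. Of all peaks, 243 (19.1%, 16.99 to 21.4) were centred in coding exons, 207 (16.3%, 14.3 to 18.4) in 3' UTRs and 56 (4.41%, 3.35 to 5.68) in 5' UTRs. Among the peaks with a host gene, these were 2.98, 3.44 and 2.63 times the share given by random placement, and 4.93, 3.93 and 3.38 times with structural RNA and mitochondria left out. Introns held 186 peaks (14.6%, 12.7 to 16.7), 0.285 times the placed share. Placement was uniform over the gene, with 66.8% of placements in introns, and did not weight exons and introns by their RNA abundance. These ratios therefore do not separate binding from the abundance of exon and intron RNA. Non-coding exons held 285 peaks (22.4%, 20.2 to 24.8), of which 137 were on snoRNAs or Cajal body RNAs, 66 on long non-coding RNAs and 39 on other small RNAs. The remaining 294 peaks (23.1%, 20.8 to 25.5) were antisense to a gene or outside genes. They included 269 on the strand opposite a nuclear gene, with a median width of 21 nt and no height above 7.

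The authors' own region column gave introns 375 peaks (29.5%, 27.0 to 32.1) and non-coding exons 140. Of those 375 intron peaks, 138 (36.8%, 31.9 to 41.9) lay on a snoRNA inside the intron. The region was the same in both for 80.6% of peaks. Peaks under 25 nt made up much of the antisense group, which was 9.45% of peaks once these were left out.

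**Figure D3:**
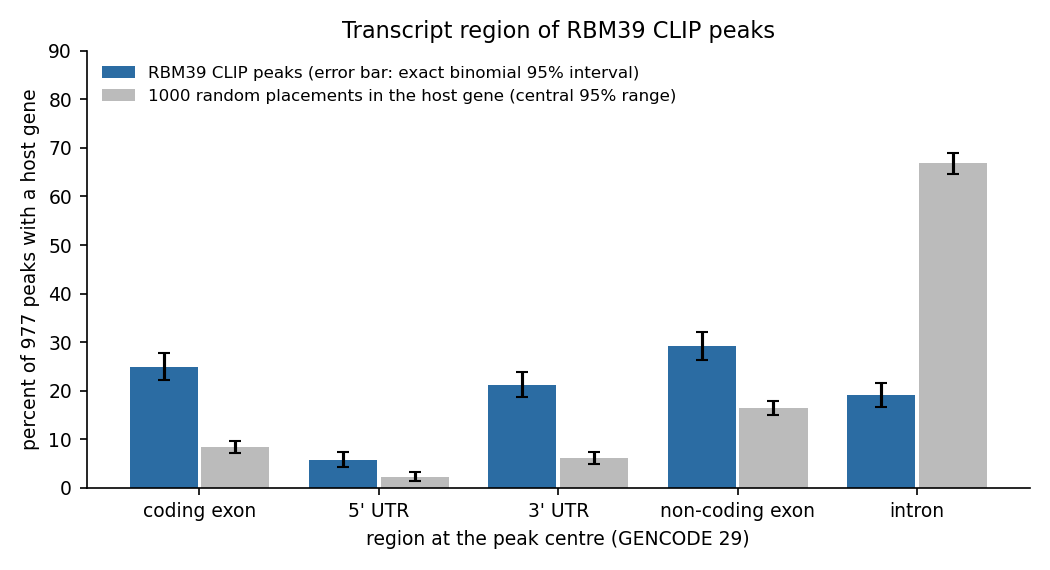
Percent of the 977 peaks with a host gene by region at the peak centre, beside 1000 random placements in the same genes. Blue bars carry exact binomial 95% intervals and grey bars the central 95% range of placements. Coding exons, UTRs and non-coding exons lie above placement and introns below. Placement does not match the abundance of exon and intron RNA.

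The genes with most peaks outside snoRNA hosts had their peak centres in coding exons and UTRs. Of these peaks, 6 of SLC38A2 and 2 of VMP1 reached into an intron. In B2M, 2 peaks each crossed a 3' splice site of only 1 transcript, classed as a target of nonsense-mediated decay. The authors' column put both of these B2M peaks wholly in exons. SLC38A2, an amino acid transporter gene on chromosome 12, had 12 peaks with 137 reads: 6 in coding exons, 4 in the 3' UTR and 2 in the 5' UTR, the tallest with a height of 15. B2M, the light chain of MHC class I, had 8 peaks, 4 of them in the 3' UTR, with a greatest height of 11. MAT2A, which makes S-adenosylmethionine, had 8 peaks, all in the 3' UTR by GENCODE 29 (chromosome 2, 85543432 to 85544783), with heights from 4 to 6; the authors' column put 2 of them in an intron. VMP1, an autophagy gene, had 6 peaks, 3 in coding exons and 3 in the 3' UTR, with heights from 5 to 9, and 1 of them held a word of the sequencing adapter. SNHG17 had 6 peaks, 5 of them on snoRNAs. MT-ND5 and MT-ND4, mitochondrial genes for complex I subunits, had 9 and 7 peaks on their own strand.

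RBM39 is related to U2AF2, so the position of peaks relative to splice sites was the second question. Peaks that crossed a splice site crossed the 3' site in nearly every case. Among 732 peaks off structural RNA in genes with introns, 63 (8.61%, 6.68 to 10.9) crossed a 3' splice site only, where random placement gave a mean of 8.43 and at most 18 in 1000 placements. A 5' splice site only was crossed by 4 peaks (0.546%, 0.149 to 1.39), where placement gave 9.24. The 1 peak that crossed both kinds was left out, as were such placements. Of the 67 peaks that crossed 1 kind of site, 94.0% (85.4 to 98.3) crossed the 3' site. This count was chosen after seeing the data. Its placements were anywhere in the host gene, and none were made within the same region. The excess over placement is therefore not separated from that of exons in general. With 1 nt instead of 5 nt required on each side 79 peaks crossed a 3' site only and the share was 80.6%, and with 10 nt it was 96.3% (52 peaks against 2).

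The crossing peaks lay in 54 genes, had a median width of 45 nt and reached a median of 20 nt into the intron of the annotated site. That part can be exon in other transcripts, and 8 of 61 crossed sites in protein-coding genes were used by no protein-coding transcript. The authors' column put some crossing peaks wholly in exons, such as 2 of B2M, 1 of HNRNPA2B1, 1 of SRSF1 and 1 of SRSF11. SLC38A2 had 6 of them, which were all of its coding exon peaks. The tallest (chromosome 12, 46362603 to 46362659, minus strand) had a height of 15 and reached 21 nt into the intron. Of the 5 SR protein genes with a peak, 4 had a crossing peak: SRSF1, SRSF2, SRSF5 and SRSF11. No random gene lists were drawn for this count. CCNL1 and CCNL2, which encode cyclins linked to splicing, HNRNPA2B1, LUC7L3 and IGF1R each had 1.

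**Figure D4:**
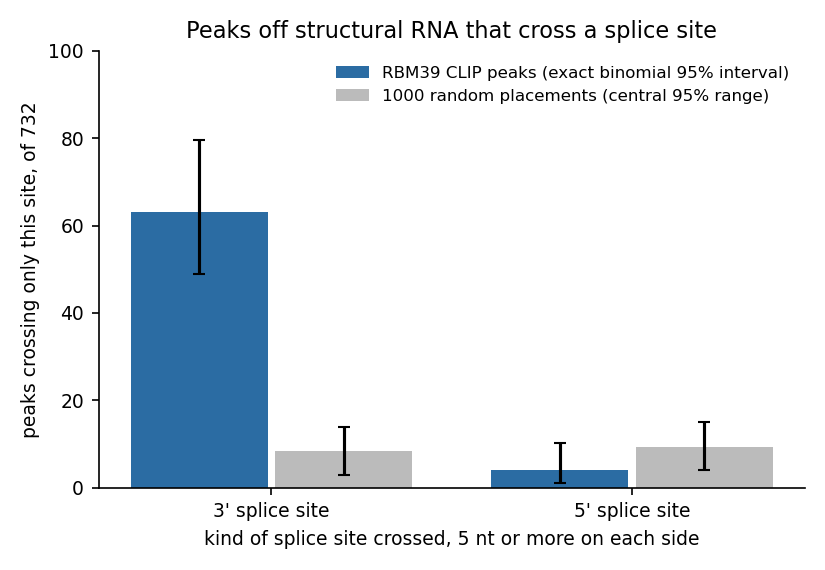
Number of the 732 peaks off structural RNA that cross only an annotated 3' or only a 5' splice site, with at least 5 nt on each side; 1 peak that crosses both is left out. Blue bars are peaks with exact binomial 95% intervals and grey bars are means of 1000 random placements with their central 95% range; 63 peaks cross only a 3' site and 4 only a 5' site.

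By the measure fixed beforehand, which used peak centres within 100 nt of a site and included structural RNA, 876 peaks were counted. The exon side of 3' splice sites held 175 (19.98%, 17.4 to 22.8), 4.14 times placement anywhere in the gene, and the exon side of 5' splice sites held 161 (18.4%, 15.9 to 21.1), 3.59 times. Beside placement within the same region these ratios were 1.06 (0.924 to 1.21) and 0.968 (0.836 to 1.11), so within 100 nt neither excess stood out from that of exons in general. Within 50 nt they were 1.35 (1.13 to 1.59) and 0.765 (0.602 to 0.957). The intron side of 3' sites held 52 peaks, 1.15 times placement anywhere (0.869 to 1.5005) and 1.14 times same-region placement (0.860 to 1.48). These were 1.53 (1.07 to 2.11) and 1.45 (1.02 to 2.00) within 50 nt, and 1.62 (1.38 to 1.89) and 1.60 (1.36 to 1.87) within 200 nt. With structural RNA left out they were 1.46 (1.06 to 1.95) and 2.07 (1.5001 to 2.76), with GENCODE basic 0.807 (0.555 to 1.13) and 1.17 (0.807 to 1.64), and for the 635 tallest peaks 1.10 (0.764 to 1.52) and 0.929 (0.646 to 1.28). The intron side of 5' sites held 64 peaks, 1.30 times placement anywhere (1.01 to 1.64) and 1.24 times same-region placement (0.963 to 1.57). These were 0.892 (0.596 to 1.28) and 1.20 (0.803 to 1.72) without structural RNA, 0.708 (0.421 to 1.11) and 0.669 (0.398 to 1.05) within 50 nt, 1.28 (1.07 to 1.51) and 1.24 (1.04 to 1.47) within 200 nt, and 1.22 (0.915 to 1.60) and 1.36 (1.02 to 1.77) with GENCODE basic.

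RBM39's own transcript carried 1 peak, of 4 reads and height 4 (chromosome 20, 35740585 to 35740615, minus strand). The authors' column put it in an intron, and GENCODE 29 put its centre in a retained intron of a non-coding RBM39 transcript. It crossed the 3' splice site of a 73 nt exon (35740525 to 35740597), with 18 nt in the intron. That splice site is annotated in 9 RBM39 transcripts, 7 of them classed as targets of nonsense-mediated decay and 0 as protein-coding.

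Genes for splicing regulators were among those with peaks. SR protein genes had a peak in 5 of 16, where random lists had 0.332 on average and 0 of 10000 lists reached 5. SRSF5 had 5 peaks, SRSF2 had 3 in its 3' UTR by GENCODE 29, 1 of them in an intron by the authors' column, with a height of up to 9, SRSF11 had 2 and SRSF1 had 1. The hnRNP list had 5 of 24 (random mean 0.517, reached by 0.01% of lists), led by HNRNPH1 with 4 peaks, HNRNPA3 and PCBP2 with 3 each and HNRNPA2B1 with 2. The 635 tallest peaks left 3 of the hnRNP genes and 4 of the SR protein genes. None of the peaks in either list lay on structural RNA. The list of U2 snRNP and 3' splice site factors had 2 of 24, RBM39 and SF3B3, and 10.9% of random lists reached that number. The SF3B3 peak was on a snoRNA. Other spliceosome proteins had 2 of 22, LUC7L3 with 4 peaks and SNRPB with 1 on a snoRNA, a number that 10.2% of lists reached. Among spliceosomal snRNAs, RNU4-2, RNU4ATAC and RNU4-1 had 1 peak each, with heights of 10, 13 and 4. Copies of U1, U2, U4, U5 and U6 share sequence, so values for single copies, RNU4-1 and RNU4-2 among them, are uncertain.

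Lists of highly expressed genes owed most of their peaks to snoRNAs. Cytosolic ribosomal protein genes had a peak in 22 of 79 (random mean 1.41), and 37 of their 42 peaks lay on snoRNAs. The most were in RPL23A with 5, and in RPL13A and RPS8 with 4 each. Off structural RNA, 3 of the 79 had a peak and 7.41% of random lists reached that number. Translation factors had 9 of 26, with 14 of 20 peaks on snoRNAs, among them all 5 peaks of EIF4A2 and all 5 of NCL (nucleolin). EIF4H had 3 peaks and PABPC1 had 2, none on a snoRNA, although 1 EIF4H peak (chromosome 7, 74174398 to 74174414) held an adapter word. Off structural RNA, 3 of the 26 genes had a peak and 1.15% of random lists reached that number. Other abundant non-coding RNAs had 9 of 16. These included SNHG1, SNHG16 with 3 snoRNA peaks, SNHG5 with 2, and GAS5. RMRP, the RNA of RNase MRP, had the peak with the most reads of all 1271, 100 reads at a height of 18, and was named after its values were seen.

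Of the breast cancer lists, estrogen receptor and luminal genes had a peak in 4 of 25 (random mean 0.675, reached by 0.5% of lists). CTSD had 4 peaks, and IGF1R, BCL2 and GATA3 had 1 each. The GATA3 peak was 3 reads and held an adapter word, and by the authors' gene column, or with the 635 tallest peaks, the list had 2 members. The cell cycle and DNA damage list had 6 of 25 (random mean 0.643, reached by 0 of 10000 lists): CCNL1 with 2 peaks, CCNL2, CDK1 and CDK6 with 1 each, and 2 further genes. The 635 tallest peaks left 3 of them. The list of genes amplified in MCF-7 had 2 of 28, VMP1 and CLTC, which 25.4% of lists reached. AP-1 and coactivator genes had 1 of 17 (EP300, 39.5% of lists) and cohesin and chromatin regulators 1 of 20 (STAG1, 51.2% of lists). Markers of other cell types had 0 of 25. Mitochondrial genes had 6 of 15, led by MT-ND5, MT-ND4, MT-ND6 with 4 peaks and MT-CO1 with 3.

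Sequence preference was the last comparison. In 696 exonic peaks, 31193 nt in all, polypyrimidine hexamers were less frequent than at random positions of the same region (ratio 0.626, 0.508 to 0.763), as were 5' splice site hexamers (0.370, 0.160 to 0.730) and 3' splice site hexamers (0.672, 0.443 to 0.977). The last interval held 1 with 1 peak per gene (0.650, 0.356 to 1.09) and without structural RNA (0.722, 0.435 to 1.13). The polypyrimidine hexamers differed: TTTTTT had a ratio of 0.464 with 38 occurrences, and CCTTTT had 0.570. Ratios for TTTCTT, CTTTTC and TCTTTC were 0.944, 0.826 and 0.807. No intronic peak could be included, nor any peak with a base outside annotated exons, and 203 of the 243 coding exon peaks were used. Intron sequence beside splice sites was thus counted only where an annotated transcript retains it. The ratios of polypyrimidine and splice site hexamers therefore do not bear on a preference for sequence at splice sites. Purine GA repeats (1.03, 0.808 to 1.30), GT repeats (1.17, 0.825 to 1.60), G runs (1.15, 0.771 to 1.65) and poly(A) signals (0.808, 0.512 to 1.21) had intervals that held 1, although against flanks the ratio for GT repeats was 0.655 (0.458 to 0.906) and without structural RNA that for G runs was 1.60 (1.03 to 2.36). Of all hexamers seen at least 20 times, CGACGA had the highest ratio, 17.2, with 22 occurrences, followed by CCGACG at 9.90. Both lie in the 5' adapter of the small RNA kit. TGATGA, the usual box C motif of C/D snoRNAs, came next at 3.73 with 55 occurrences, and CTGATG, TCTGAT and GTCTGA were also among the top 10.

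Words of 8 nt from the kit's 5' adapter stood in 54 of the 986 peaks with a known sequence (5.48%, 4.14 to 7.09), against 9 of 1590 flanking windows (0.566%, 0.259 to 1.07). Shuffled adapters gave a median of 6 and at most 19. The share was 10.2% (7.56 to 13.4) in peaks under 25 nt and 1.65% (0.756 to 3.11) in wider ones. Leaving these peaks out changed no list count by more than 1.5 times.

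**Figure D5:**
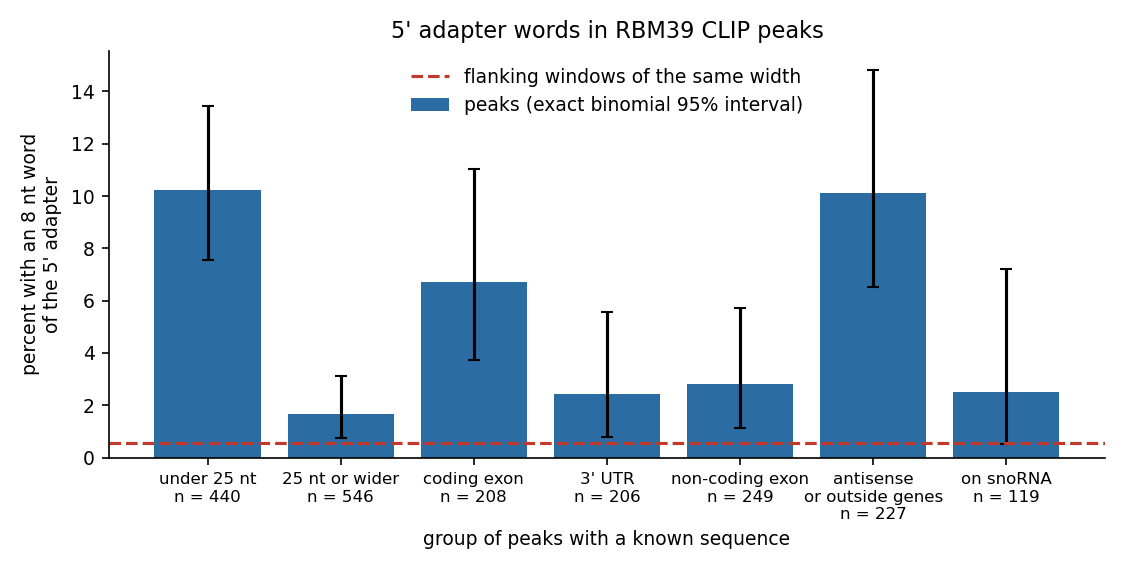
Percent of peaks that hold an 8 nt word of the kit's 5' adapter, by group of peaks with a known sequence, with exact binomial 95% intervals and n. The dashed line is the share in flanking windows, 0.566%; peaks under 25 nt reach 10.2% and antisense peaks 10.1%.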

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

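Of 230 alternative values, 171 stayed within the main 95% interval or within 1.5 times the main count, 57 moved further and 2 crossed 1 from a main interval that excluded it. Of 106 ratios, 10 more changed side of 1 from an interval that held it, 6 intervals ceased to exclude 1 and 12 newly excluded it. The excess of coding exons and UTRs over placement, the intron deficit and the share of crossings at the 3' site kept their direction in all alternatives run. None of these alternatives weighted placement by the abundance of exon and intron RNA. The cause was not tested except where the setting removes the peaks concerned. Alternatives chosen after seeing the data were GENCODE basic, peaks of at least 25 nt, peaks outside the mitochondrial genome, peaks without adapter words, peaks off structural RNA for splice sites, lists and hexamers, and those of splice site crossing. No paired analysis was possible because each antibody had 1 library. In all, 42.5% of peaks rest on 3 reads.

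The 2 reversals were of the intron side of 5' splice sites against placement anywhere in the gene, 0.708 within 50 nt and 0.892 off structural RNA. The 635 tallest peaks gave shares of 31.97% for non-coding exons, 9.29% for introns and 18.6% antisense or outside genes. Their ratios to placement were 2.13 for coding exons, 0.190 for introns, 2.85 for the exon side of 5' splice sites and 2.92 for that of 3' sites. With 1 peak per gene, shares were 16.5% for coding exons, 14.1% for 3' UTRs and 27.95% antisense or outside, with ratios of 3.56 for coding exons and 0.326 for introns, and 100% of crossings were at the 3' site. The authors' region column gave 14.005% for 3' UTRs, 11.01% for non-coding exons and 29.5% for introns. Off structural RNA, 3' UTRs had 19.2%, non-coding exons 11.4%, introns 17.5% and antisense or outside 26.1%. In the same setting, ratios were 4.93 for coding exons, 3.93 for 3' UTRs and 1.45 for non-coding exons, and 5.40 and 6.29 for the exon sides of 5' and 3' splice sites. The intron side of 3' sites reached 2.07 against placement in the same region. Peaks of at least 25 nt gave 23.4% in 3' UTRs, 29.3% in non-coding exons and 9.45% antisense or outside, with ratios of 2.20 for coding exons, 1.86 for 5' UTRs and 0.242 for introns. GENCODE basic gave a ratio of 2.48 for non-coding exons and 0.807 for the intron side of 3' sites.

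Within 50 nt, ratios to placement anywhere were 2.83 and 5.34 for the exon sides of 5' and 3' sites and 1.53 for the intron side of 3' sites. Against the same region they were 0.765 and 1.35 for the exon sides and 0.669 for the intron side of 5' sites. Within 200 nt, the intron side of 3' sites had 1.62 (1.38 to 1.89) anywhere and 1.60 (1.36 to 1.87) in the same region. With 1 nt on each side, 80.6% of crossings were at the 3' site. The 635 tallest peaks left 3 hnRNP genes, 2 estrogen receptor and luminal genes, 0 AP-1 and coactivator genes and 3 cell cycle genes with a peak. The authors' gene column gave 2 estrogen receptor and luminal genes. Off structural RNA, genes with a peak numbered 1 for U2 snRNP factors, 1 for other spliceosome proteins, 0 for snRNAs, 1 for other abundant non-coding RNAs, 3 for ribosomal proteins, 3 for translation factors and 0 for mitochondrial genes. Against flanks, GT repeats had a ratio of 0.655 (0.458 to 0.906).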

Other observations

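Smaller classes of RNA also had peaks; the RNAs in this paragraph other than RBM39 and the mitochondrial genes were chosen after their values were seen. MicroRNA loci had 10 peaks of 22 to 25 nt, with heights from 3 to 5. They included MIR411, MIR127, MIR494 and MIR136 of the imprinted microRNA cluster on chromosome 14, and MIRLET7G, MIR99B and MIR125A. RNase P RNA (RPPH1) had a peak of 25 reads and height 9, 7SK a peak of 17 reads and height 10, and telomerase RNA (TERC) a peak of 8 reads and height 6. The mitochondrial genome had 28 peaks on the plus strand and 23 on the minus strand. Of the peaks antisense to mitochondrial genes, 8 lay opposite MT-ND5 and 5 opposite MT-ND4. Of the 3' splice sites crossed in 52 protein-coding genes, 8 of 61 (13.1%, 5.84 to 24.2) were used by no protein-coding transcript, against 13.8% of all 991 sites in these genes. The sites used only outside coding transcripts, like the one crossed in RBM39, were thus not detectably over-represented among crossed sites.

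In the patterns below, 2 tests were set before their results were seen: the overlap of antisense peaks with the other strand, and the 3' splice site ratio off structural RNA. The other tests in this part were chosen after the result was seen. In 2 of these, the bounds were also revised after their values were known: RNY5, which GENCODE 29 lacks, was dropped from the panel of stable RNAs, and an interval that spans 0 was taken to leave read support open, where it had first been counted against that explanation. In 1 more, on spliced junctions, the peaks counted were widened from crossings of at least 5 nt to those of at least 1 nt after the values were known, with the bounds kept.

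Peaks off structural RNA crossed 3' splice sites far more often than 5' sites. Unspliced RNA sampled without regard to the site would give both alike, and 94.0% (85.4 to 98.3) at the 3' site, which is the pattern itself, argues against that. These crossings were counted off structural RNA, so the test of nearby snoRNAs does not bear on them. In the measure fixed beforehand, over peak centres within 100 nt, leaving out structural RNA took the ratio for the intron side of 3' sites from 1.15 (0.869 to 1.5005) to 1.46 (1.06 to 1.95), which argues against snoRNAs as the source of peaks counted there beyond placement; the first interval held 1, and GENCODE basic gave 0.807 with structural RNA included. Reads over spliced junctions aligned a few nt past the exon end cannot be told apart from contact with the intron. Over all 79 peaks that crossed only a 3' site, by 1 nt or more, the median was 17 nt in the intron, while the lower quartile of 9 nt was short of the 10 nt needed to argue against them; 58 of the 79 (73.4%, 62.3 to 82.7) reached 10 nt or more. No biological explanation was tested, and a preference of ultraviolet light for uridine-rich tracts and the IgG background stay open.

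The tallest peaks lay on snoRNAs. Of 138 peaks in snoRNA-holding introns, 96.4% (91.7 to 98.8) were centred on the snoRNA and 5 lay elsewhere in the intron. SnoRNAs make up 0.751% of the length of all 558 such introns annotated, which include introns without a peak. That share is thus not the one in introns that carried peaks, and heights follow RNA abundance as well as binding. Peaks followed the snoRNA rather than the whole intron, but contact with the unspliced host intron cannot be excluded. Carry-over of abundant stable RNAs cannot be told apart from binding. In the panel of other stable non-coding RNAs, 6 of 15 had a peak, between the bounds set for either reading. The IgG library that would decide between them was not analysed here. No biological explanation was tested, since the design names none.

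Narrow and antisense peaks made up much of the list. Mates counted on the wrong strand are argued against, as 0 of 269 nuclear antisense peaks overlapped a peak on the other strand (upper bound 1.36%), although 11 of 20 mitochondrial ones did. Short tags aligned by chance may account for part of them, but the test by width restates the pattern itself. Of nuclear antisense peaks, 84.0% were under 25 nt against 47.2% in coding exons, a difference of 36.8 points (28.6 to 44.4). For peaks with 3 reads the difference was 3.22 points (-5.67 to 12.0), which leaves read support open. Adapter sequence in reads is consistent with the 54 peaks that held a word of the 5' adapter, against at most 19 for shuffled adapters. Of the 207 nuclear antisense peaks with sequence, 11.1% (7.18 to 16.2) held such a word. Only exact 8 nt words were counted, so shorter or mismatched adapter remnants could be missed. Whether adapter sequence accounts for most antisense peaks is therefore left open.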
